A study of Bos taurus with 7 samples.

How the data were processed

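RNA sequencing libraries of bovine blastocysts were compared between 3 groups of oocyte treatment: control (2 libraries), etomoxir (3 libraries) and IO+DHEA (2 libraries). Groups were taken from the treatment label of each sample, and the numbers from the sample titles. Per the labels' protocols, complementary DNA was made from total RNA with a SMARTer kit for ultra-low input and libraries with a Nextera XT kit. Neither step is known to mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

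The deposited table held raw counts per Ensembl gene ID, made by the authors before any normalization. Per the submitters' processing notes, the tools were cutadapt 1.18, STAR 2.7.9a and featureCounts 2.0.1, and the genome build was ARS-UCD1.2. The annotation release and the settings for strand, multi-mapping reads and read pairs are not given in the sources used here. Genes that share reads with a near-identical copy are therefore uncertain. The values were whole numbers with a different total in each library. Among counts of 1 to 20, 67.7% to 78.3% were even, where single counting gives no preference for even numbers, so a count may not equal 1 sequenced fragment. The 78.3% was that of IO+DHEA library 1, and the next highest share was 71.2%, in IO+DHEA library 2.

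Total counts were 87096323 and 111170317 in the control libraries, 122061453, 84739741 and 88298457 in etomoxir, and 90842836 and 105394867 in IO+DHEA. Levels are given on the counts-per-million (CPM) scale. If 1 count is 1 fragment, a count of 0 allows up to 3 counts, which is 0.0246 to 0.0354 CPM in a library. The 10 most abundant genes took 10.5% to 12.3% of the counts. Thinned to the total of the smallest library, the number of genes detected ranged from 12985 in IO+DHEA library 1 to 15811 in etomoxir library 1. To look for a library deposited under more than 1 name, replicates were compared by a chi-square of their counts over genes, which was 141 to 883 per degree of freedom, so no pair agreed within sampling noise. This does not show that the replicates were biologically separate.

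Counts were analysed in R 4.3.3. Genes were kept by the filterByExpr function of edgeR 4.0.16, with a minimum count of 10 and a minimum total of 15, and scaled by TMM. All 7 libraries entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest) with 3 group terms and 4 residual degrees of freedom. The fit assumes 1 spread per gene for all 3 groups. The tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of the 3 comparisons. Standard errors were derived from the log2 fold change and the test statistic. CPM values use TMM-scaled totals, and log2 CPM uses a prior count of 2. Library measures were compared by exact two-sided permutation tests, which cannot go below 0.333 for 2 against 2 libraries or 0.2 for 2 against 3. Figures were drawn with matplotlib 3.10.9.

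The analysis was tested on simulated data with 200 of 15134 genes changed. For etomoxir against control it recovered 6%, 34%, 44% and 62% of genes changed by 2, 4, 8 and 16-fold, with 5 false calls among 78. For IO+DHEA against control these shares were 2%, 22%, 46% and 50%, with 3 false calls among 63. For etomoxir against IO+DHEA they were 0%, 28%, 40% and 50%, with 5 among 64. The simulation gave all groups 1 spread per gene, while the real IO+DHEA libraries differed more from each other. These shares and false calls therefore do not measure the error of the calls in the IO+DHEA comparisons.

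The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. That rule took, per comparison, the called genes with a symbol, a mean of at least 1 CPM and no overlap between libraries of the groups, with the largest rises and falls, together with members of 26 gene lists and genes of the inhibited pathways and embryonic lineages. No symbol could be matched to the Ensembl IDs, so the symbol part of the rule was dropped. The gene that changed in etomoxir, the largest rise and the 2 largest falls in IO+DHEA are given by ID. None of the 26 lists, which covered metabolism, stress, lineage and other cell types, was tested, for the same reason. Mitochondrial and X-chromosome shares were not analysed here, since no annotation was used.

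Alternatives were median-of-ratios and upper quartile scaling, no filter and a stricter filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust estimation, a fit of the compared groups alone, a replicate block, leaving out each library in turn, an adjusted p under 0.1 and a log2 fold change of at least 1. Counts divided by 2 and rounded were added after the data were seen.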

Results

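The data were gene-level read counts from RNA sequencing of bovine blastocysts. A blastocyst is the embryo at the stage when an outer trophectoderm, an inner cell mass and a fluid-filled cavity have formed. The inhibitors were present earlier, while the oocytes matured in vitro, so the embryos were profiled after the treated stage. The 7 libraries formed 3 groups: 2 control libraries, 3 libraries from oocytes matured with etomoxir and 2 from oocytes matured with IO+DHEA. Etomoxir inhibits carnitine palmitoyltransferase 1, which admits long-chain fatty acids to mitochondrial oxidation, and stood for inhibition of fatty acid metabolism. IO+DHEA stood for inhibition of glucose metabolism. DHEA is the usual abbreviation of dehydroepiandrosterone, and what IO stands for is not given in the sources used here. The labels do not say how many embryos went into a library or whether replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

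The libraries held 84739741 to 122061453 counts, with 87096323 and 111170317 in control and 90842836 and 105394867 in IO+DHEA. Of the 27607 Ensembl gene IDs in the table, 8992 had 0 counts in all 7 libraries and 15134 had enough counts to be tested. The files do not pair these IDs with gene symbols, and 0 of them were found in the reference table used here, so genes are given as counts of genes and by at most 2 IDs that rose and 2 that fell.

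The IO+DHEA libraries differed most from the rest, and they differed about as much from each other. Over the 7610 genes with a mean of at least 5 CPM (the counts-per-million scale), the median absolute log2 difference between the control libraries was 0.27 and between pairs of etomoxir libraries 0.21 to 0.26. Control and etomoxir libraries differed by 0.25 to 0.33, about the spread within either group. The IO+DHEA libraries differed from each other by 0.59, from the controls by 0.61 to 0.78 and from the etomoxir libraries by 0.65 to 0.81. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.943 within control, 0.943 to 0.948 within etomoxir, 0.930 to 0.949 between these groups, and 0.856 between the IO+DHEA libraries. It was 0.874 to 0.881 between IO+DHEA and control libraries and 0.864 to 0.898 between IO+DHEA and etomoxir libraries. By r the IO+DHEA libraries were thus less alike than either was to any other library. Component 1 of a principal component analysis held 39.9% of the variance and set IO+DHEA library 1 apart, and component 2 held 24.5% and set IO+DHEA library 2 apart.

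Fewer genes were detected in IO+DHEA library 1. It had at least 1 count for 12990 genes, against 15056 in IO+DHEA library 2, 15253 and 15793 in the controls and 15504 to 15898 in the etomoxir libraries. The group means were 14023 ± 1461 genes in IO+DHEA (SD, n = 2), 15523 ± 382 in control (SD, n = 2) and 15705 ± 197 in etomoxir (SD, n = 3). The exact two-sided permutation p was 0.333 for IO+DHEA against control and 0.2 for etomoxir against IO+DHEA, the smallest these group sizes allow, and 0.6 for etomoxir against control. Of the 10719 genes with a mean of at least 1 CPM on the library totals before TMM scaling, 313 had 0 counts in IO+DHEA library 1, 44 in IO+DHEA library 2 and 5 to 31 in each of the other libraries. On the same unscaled totals, none of the 2996 genes with a mean of at least 50 CPM had 0 counts in any library. IO+DHEA library 1 also had the lowest TMM factor, 0.840, against 0.982 to 1.09 in the other libraries.

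**Figure D1:**
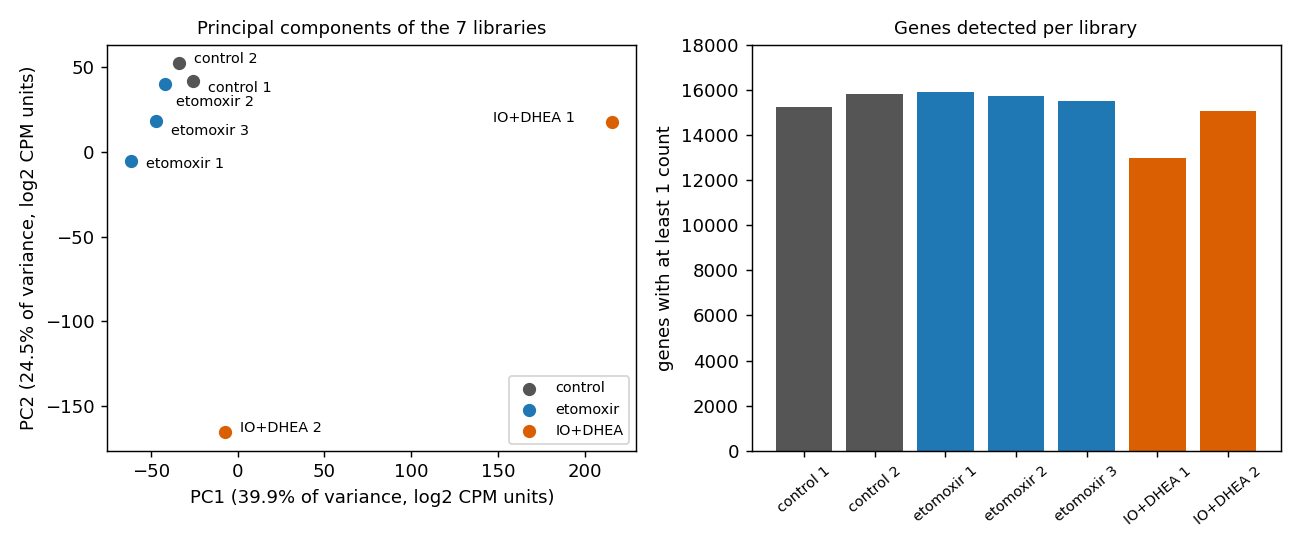
The left panel places each of the 7 libraries by its first and second principal components of log2 CPM, coloured by group, and the right panel gives the number of genes with at least 1 count per library. Control and etomoxir libraries lie together, IO+DHEA library 1 lies apart on the first component with 12990 genes detected, and IO+DHEA library 2 lies apart on the second with 15056.

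Etomoxir against control asked whether inhibiting fatty acid metabolism during maturation altered the transcripts of the blastocyst. By the number of genes called, the etomoxir group was close to the control group. Of 15134 genes, 1 was higher in etomoxir and 0 were lower by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The gene that rose, ENSBTAG00000043960, was at 1.21 ± 0.27 CPM in control (SD, n = 2) and 60.1 ± 14.2 CPM in etomoxir (SD, n = 3). Its log2 fold change was 5.64 ± 0.36 (SE), a 49.8-fold rise with an edgeR adjusted p of 0.00722, and it was higher in 3 of 3 etomoxir libraries. In IO+DHEA the same gene was at 68.0 ± 9.67 CPM (SD, n = 2), with a log2 fold change over control of 5.82 ± 0.37 (SE) and an edgeR adjusted p of 0.00223, so both treated groups stood above both controls.

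The next smallest edgeR adjusted p for etomoxir against control was 0.823. At an unadjusted p under 0.05 there were 514 genes, 3.40% of those tested, and the median absolute log2 fold change was 0.32. An edgeR fit of control and etomoxir alone also called 1 gene, but had 1287 of 14659 genes at an unadjusted p under 0.05. The lower number thus depended on the spread shared with the IO+DHEA libraries. Libraries of the groups did not overlap for 25.3% of the genes tested, where chance gives 20% if all libraries vary alike. Genes of at least 5 CPM that were over 4-fold apart between 1 etomoxir and 1 control library had a median difference in the same direction of 0.13 to 0.80 on the log2 scale in another etomoxir library against the other control. The 95% limits lay above 0 in 3 of these 6 checks, from 0.514 to 1.08 for the highest. These limits resample genes, which are not independent replicates, and leave out the spread between libraries. Not every assignment of libraries was run. DESeq2 called 61 genes, 58 higher and 3 lower, among them the gene named above, and limma-voom called 0, with 572 at an unadjusted p under 0.05. The edgeR adjusted p of ENSBTAG00000043960 was 0.207 without control library 1, 0.294 without control library 2 and 0.102 without etomoxir library 2. Over all alternatives the adjusted p of this gene ranged from 1.57e-64 with DESeq2 to 0.294, and from 0.000425 to 0.294 among the edgeR fits. In simulated data with 1 spread per gene for all groups, the same test at these group sizes recovered 34% of 4-fold and 62% of 16-fold changes. Changes of a few-fold could therefore go uncalled.

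IO+DHEA against control asked the same of inhibiting glucose metabolism. Here 1050 of 15134 genes changed, 6.94% of those tested, with 323 higher and 727 lower in IO+DHEA by edgeR at an adjusted p under 0.05. The median log2 fold change was 1.33 among the genes that rose and -1.68 among those that fell. Changes of over 4-fold were found for 50 of the genes that rose and 247 of those that fell. Of the genes that fell, 41 were at 0 counts in a whole group, as was 1 of those that rose. Setting these at the bound that 3 counts over the group allow left the medians and the counts of 4-fold changes at the same values.

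Abundant transcripts were called changed most often. Among the 2994 genes with a mean over 50 TMM-scaled CPM, 18.1% changed, 210 higher and 332 lower. The larger direction at this level turned with the settings, to 373 higher and 226 lower with upper quartile factors and 497 and 398 with the stricter filter. The share was 8.82% of the 4616 genes at 5 to 50 CPM, 94 higher and 313 lower, and 1.34% of the 7524 genes under 5 CPM, 19 higher and 82 lower. The share was also higher over 50 CPM than under 5 CPM in each fit without 1 library, the lowest being 1.04% against 0.0266% without control library 2. The precision of a fold change also rises with the count, so these shares do not compare the size of the effect between levels. Among the 500 genes most abundant in control, 26 were higher and 55 lower in IO+DHEA, and 52 were higher and 36 lower with upper quartile factors. In etomoxir, 0 of these 500 were called in either direction by edgeR. Over all genes 514 reached an unadjusted p under 0.05 by edgeR, or 1287 in a fit of control and etomoxir alone. DESeq2 called 61 and limma-voom 0.

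The excess of lower genes depended on the scaling. With median-of-ratios factors 410 genes were higher and 670 lower, and with upper quartile factors 588 were higher and 514 lower, which moved the median log2 fold change of all genes from -0.01 to 0.19. Among changes of over 4-fold, falls outnumbered rises under these scalings too, with 230 lower and 62 higher, and 191 lower and 95 higher. With the stricter filter on low counts the excess was smaller, with 164 lower and 74 higher. Some of the falls of over 4-fold were in genes under 5 CPM, where loss of transcripts from a library and a response cannot be told apart. The number of genes also depended on single libraries. It was 72 without control library 1, 47 without control library 2, 332, 271 and 110 without etomoxir libraries 1, 2 and 3, 2191 without IO+DHEA library 1 and 3707 without IO+DHEA library 2. DESeq2 called 2883 genes, and a fit of these 2 groups alone called 0 by edgeR, with 2530 at an unadjusted p under 0.05. The 1050 calls thus rest on the assumption that the 3 groups share 1 spread per gene. All 1050 genes had libraries that did not overlap between the groups. Among all genes tested this held for 49.6%, where chance gives 33.3% if all libraries vary alike. The IO+DHEA libraries varied more than the controls, which raises the share that chance gives. No excess over chance is therefore read from it.

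**Figure D2:**
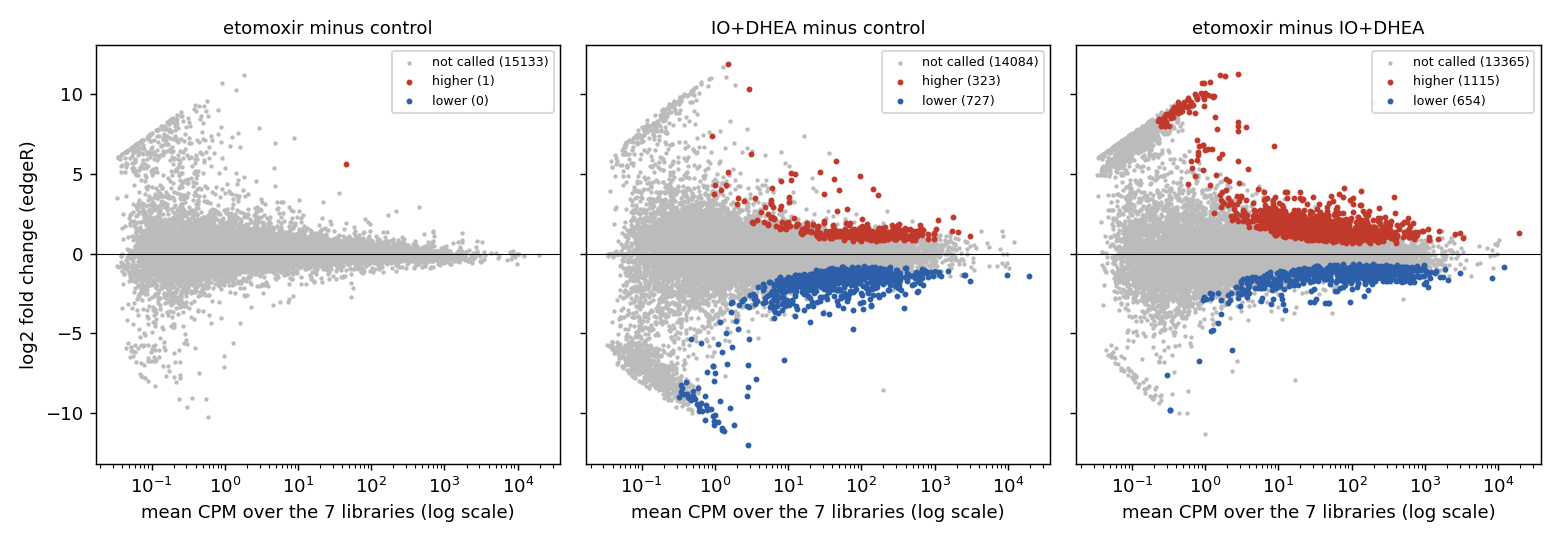
Each panel plots the log2 fold change of the 15134 tested genes against their mean CPM on a log scale for 1 of the 3 comparisons, with genes at an edgeR adjusted p under 0.05 in red (higher) or blue (lower) and the others in grey. Etomoxir against control has 1 coloured gene, IO+DHEA against control 1050 and etomoxir against IO+DHEA 1769.

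**Figure D3:**
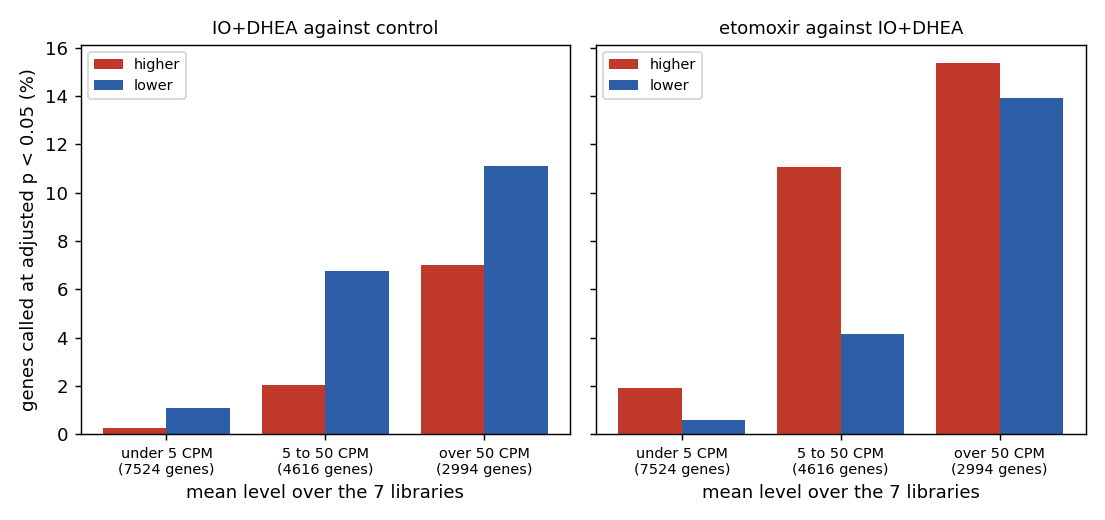
Bars give the percent of genes higher and lower at an edgeR adjusted p under 0.05, for genes under 5, at 5 to 50 and over 50 mean CPM, in IO+DHEA against control and in etomoxir against IO+DHEA. The share rises with level in both comparisons, from 1.34% to 18.1% and from 2.54% to 29.3% with both directions added, while the larger direction over 50 CPM turns with upper quartile factors.

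Of the genes that rose in IO+DHEA with a mean of at least 1 CPM, ENSBTAG00000003515 had the largest fitted change. It had 0 counts in both controls and was at 4.88 ± 4.49 CPM in IO+DHEA (SD, n = 2), 1.70 CPM in library 1 and 8.05 in library 2. This was at least 319-fold higher, taking 3 counts over the control group as the limit of a count of 0 and 1 count as 1 fragment. The edgeR adjusted p was 0.0200. The limit was 177-fold and 142-fold without control libraries 1 and 2, 527-fold without IO+DHEA library 1 and 112-fold without IO+DHEA library 2. Etomoxir lay between, at 0.236 ± 0.127 CPM (SD, n = 3), and IO+DHEA was also higher than etomoxir, with an edgeR adjusted p of 0.0339 and higher values in 2 of 2 libraries.

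The genes with the largest falls went from a few CPM to 0 counts. Those given here had a mean under 5 CPM over the 7 libraries, where loss of transcripts from a library and a response cannot be told apart. Of the genes with a mean of at least 1 CPM on unscaled totals, 313 had 0 counts in IO+DHEA library 1 and 44 in IO+DHEA library 2. ENSBTAG00000012700 was at 2.86 ± 1.33 CPM in control (SD, n = 2), 1.21 ± 0.496 CPM in etomoxir (SD, n = 3) and 0 counts in both IO+DHEA libraries. It was at least 182-fold lower in IO+DHEA than in control, against 3 counts over the IO+DHEA group, with an edgeR adjusted p of 0.0141. The limit was 109.5-fold and 72.8-fold without IO+DHEA libraries 1 and 2. ENSBTAG00000039035 was at 0.951 and 9.52 CPM in the controls, 3.10 ± 3.75 CPM in etomoxir (SD, n = 3) and 0 counts in both IO+DHEA libraries, at least 333-fold lower than control with an edgeR adjusted p of 0.0452. Its limit was 606-fold without control library 1, 60.6-fold without control library 2, and 200.2-fold and 133-fold without IO+DHEA libraries 1 and 2. These limits take 1 count as 1 sequenced fragment. Most low counts were even, so a fragment may add more than 1 count, and each limit would then be lower. At most they cover counting error, since reads without molecular identifiers are not independent molecules.

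The calls of these 3 genes against control were close to the threshold. Without control library 1 or control library 2 the edgeR adjusted p was 0.0837 and 0.116 for ENSBTAG00000003515, 0.0537 and 0.0908 for ENSBTAG00000012700, and 0.0810 and 0.160 for ENSBTAG00000039035. Without etomoxir libraries 1, 2 and 3 it was 0.0550, 0.0514 and 0.0609 for ENSBTAG00000003515 and 0.0572, 0.0835 and 0.0850 for ENSBTAG00000039035. ENSBTAG00000012700 missed the threshold without etomoxir library 3, at 0.0557, and ENSBTAG00000039035 without IO+DHEA library 1, at 0.0561. Over all alternatives the adjusted p ranged from 2.68e-08 with DESeq2 to 0.175 with edgeR for ENSBTAG00000003515 and from 5.78e-08 with DESeq2 to 0.172 with edgeR for ENSBTAG00000012700. For ENSBTAG00000039035 it ranged from 7.92e-07 with DESeq2 to 0.231 with limma-voom. The directions held under each alternative run.

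**Figure D4:**
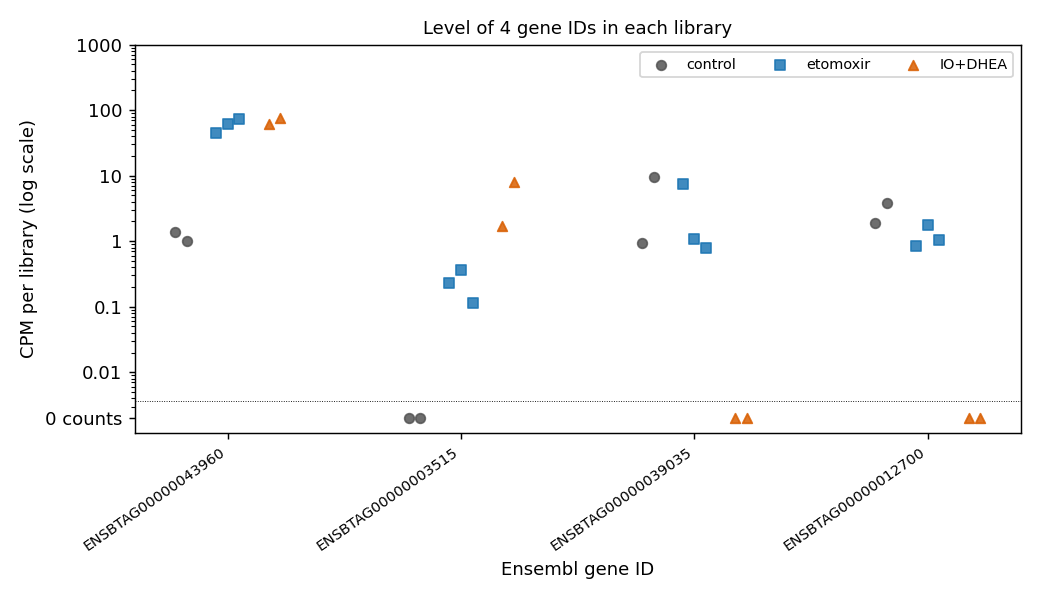
Points give the level of 4 gene IDs in each of the 7 libraries in CPM on a log scale, with libraries at 0 counts drawn on the lowest line and groups marked by colour and shape. ENSBTAG00000043960 is at 1.02 and 1.40 CPM in the controls and at 44.9 CPM or more in the treated libraries, and ENSBTAG00000012700 and ENSBTAG00000039035 are at 0 counts in both IO+DHEA libraries.

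Etomoxir against IO+DHEA set the treatments against each other. Of 15134 genes, 1769 differed, 11.7% of those tested, with 1115 higher and 654 lower in etomoxir by edgeR at an adjusted p under 0.05. The median log2 fold change was 1.52 among genes higher in etomoxir and -1.29 among genes lower. Differences of over 4-fold were found for 339 of the higher and 72 of the lower genes. Among genes over 50 CPM 29.3% differed, 460 higher and 417 lower in etomoxir, or 416 and 496 with median-of-ratios factors and 313 and 621 with upper quartile factors, against 15.2% at 5 to 50 CPM and 2.54% under 5 CPM. ENSBTAG00000039035, with 0 counts in both IO+DHEA libraries, was at least 197-fold higher in etomoxir if 1 count is 1 fragment. The edgeR adjusted p of this gene was 0.0372, with higher values in 3 of 3 etomoxir libraries. Its level was 7.42 CPM in etomoxir library 1 and 1.09 and 0.788 CPM in the other etomoxir libraries, and the limit was 59.7-fold without etomoxir library 1, and 119-fold and 78.8-fold without IO+DHEA libraries 1 and 2.

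The split again followed the scaling, with 989 higher and 782 lower by median-of-ratios factors, and 777 higher and 1072 lower by upper quartile factors. Differences of over 4-fold were mostly higher in etomoxir under both, with 295 higher and 83 lower, and 247 higher and 135 lower. With the stricter filter on low counts, 180 were higher and 59 lower. The count was 966 and 976 without control libraries 1 and 2, 262, 187 and 35 without etomoxir libraries 1, 2 and 3, and 4530 without IO+DHEA library 2, DESeq2 called 3481, and a fit of these groups alone called 932. Libraries of the groups did not overlap for 44.4% of all genes tested, where chance gives 20% if all libraries vary alike. The IO+DHEA libraries varied more, so no excess over chance is read from this share. For ENSBTAG00000039035 the edgeR adjusted p was 0.0709, 0.0823 and 0.0868 without etomoxir libraries 1, 2 and 3, and 0.0640 without IO+DHEA library 1. Over all alternatives its adjusted p ranged from 1.24e-06 with DESeq2 to 0.235 with limma-voom.

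With all 7 libraries in the fit, most genes that set IO+DHEA apart from control also set it apart from etomoxir. Of the 727 genes lower in IO+DHEA than in control, 691 were also lower than in etomoxir, and of the 323 higher genes, 260 were also higher than in etomoxir. With upper quartile factors these were 469 of 514 lower and 503 of 588 higher genes, so the excess of lower genes depended on the scaling. No gene was called in opposite directions by edgeR. The genes lower than both had a median log2 fold change of -1.71 against control and -1.70 against etomoxir, and the genes higher than both had medians of 1.32 and 1.32. Among all 727 genes lower in IO+DHEA than in control, whether or not they differed from etomoxir, etomoxir against control had a median of -0.06 and was below 0 for 438. Among all 323 higher genes its median was 0.11 and it was above 0 for 207. Both comparisons use the same controls, so chance values of the controls lean these shares the same way. Independent lists of these sizes would share 53.6 lower and 14.0 higher genes. In 20 simulations of unchanged groups that shared the same libraries, at most 3 genes were called against control, 2 against etomoxir and 1 in both, too few to set a level for lists of these sizes. Both comparisons use the same IO+DHEA libraries and a split would leave 1 library in each part, so part of the excess may come from the shared libraries. Without IO+DHEA library 1, 1195 of 1382 lower and 500 of 809 higher genes were also called against etomoxir, and without IO+DHEA library 2, 2296 of 2440 and 1081 of 1267. Without control library 1 these were 68 of 68 and 1 of 4, and without control library 2, 45 of 45 and 0 of 2. Without etomoxir library 1 they were 189 of 270 and 27 of 62, without etomoxir library 2, 134 of 225 and 23 of 46, and without etomoxir library 3, 34 of 94 and 1 of 16. The larger part of the genes was therefore not shared without etomoxir library 3, nor were most higher genes without any one of the control or etomoxir libraries.

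Fold changes of etomoxir and of IO+DHEA over the same controls had a Pearson's r of 0.358 across 15134 genes, which are not independent replicates, and a covariance of 0.493. Simulated unchanged groups that shared the 2 controls gave a mean r of 0.548 and a covariance of 0.576 (lowest 0.545, highest 0.615) when the spread was that of all 7 libraries, above the observed covariance by 0.083. With the spread of the control and etomoxir libraries they gave a covariance of 0.367 (lowest 0.341, highest 0.392), below the observed one by 0.126. With a separate control library for each treatment, r was 0.009 and the covariance 0.017 in one assignment, and 0.067 and 0.120 in the other. Without IO+DHEA library 2 the r over shared controls was 0.184.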

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

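Dividing the counts by 2 was the alternative chosen only after the data were seen. For etomoxir against control, 1 gene changed under every alternative except DESeq2 (61 genes), limma-voom (0, with 572 at an unadjusted p under 0.05), the replicate block (0, with 217) and the fits without control library 1, control library 2 or etomoxir library 2 (0, with 343, 331 and 396), so the range without single libraries was 0 to 1. For IO+DHEA against control, 1050 genes changed, and the count stayed within 1.5 times that under the other scalings, no filter, limma-voom, robust estimation, a log2 fold change of at least 1 and divided counts (977 to 1315). It was 1606 with the stricter filter, 2883 with DESeq2, 2178 at an adjusted p under 0.1, 0 with these 2 groups alone by edgeR (2530 at an unadjusted p under 0.05), 0 with the replicate block (2603) and 47 to 3707 without single libraries. For etomoxir against IO+DHEA, 1769 genes changed, with 1504 to 2173 under the other scalings and filters, limma-voom, robust estimation, a log2 fold change of at least 1 and divided counts, and 3481 with DESeq2, 2899 at an adjusted p under 0.1, 932 with these groups alone, 0 with the replicate block by edgeR (2633 at an unadjusted p under 0.05) and 35 to 4530 without single libraries. Of the 1050 genes, 985 were called in the same direction without IO+DHEA library 1 and 1048 without IO+DHEA library 2, but 70 and 45 without control libraries 1 and 2, and 330, 271 and 110 without etomoxir libraries 1, 2 and 3. A block, a smaller fit or a missing library leaves fewer residual degrees of freedom, and a lone library is assumed to vary like the other groups. Degrees of freedom alone do not account for the counts in the IO+DHEA comparisons. These counts rose without either IO+DHEA library and fell without either control library, at equal degrees of freedom. The calls rest on 1 spread per gene shared by all groups, although the IO+DHEA libraries differed more from each other. Beyond this the cause was not tested. Deviations of same-numbered libraries of different groups had correlations of -0.16 to 0.06. In a group of 2 libraries the deviations from the group mean are exact opposites, so this check holds few independent values. It cannot exclude that the numbers pair the samples. The correlation of the treatments' fold changes, 0.358, was 0.378 without a filter, 0.250 with the stricter one, 0.389 with the replicate block and 0.184 to 0.521 without single libraries; the cause was not tested. The share of higher genes in IO+DHEA against control was 30.8%, and 38.0%, 53.4%, 48.9% and 45.0% with median-of-ratios factors, upper quartile factors, the stricter filter and DESeq2. With upper quartile factors the larger direction turned in both IO+DHEA comparisons, to 588 higher and 514 lower against control and 777 higher and 1072 lower for etomoxir against IO+DHEA. The genes given by ID kept their direction under the alternatives run. The planned gene list tests were not run, since IDs and symbols could not be paired. At these totals 3 counts are at most 0.0354 CPM in a library, and levels under that cannot be told from 0.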

Other observations

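The tests of falls by level, of gaps between any pair of libraries and of separate controls were chosen only after the result was seen. Genes that separated a pair of libraries from the other 5 by at least 30-fold, in CPM on unscaled totals, were most frequent for the IO+DHEA pair, with 9, followed by 5 for control library 1 with IO+DHEA library 1 and at most 1 for each of the other pairs. The IO+DHEA pair lacked 2 genes present at 1 CPM or more in the other 5 libraries and held 1 gene at that level with 0 counts elsewhere. Control library 1 and IO+DHEA library 1 together also lacked 2 genes present in the other 5.

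The genes changed between IO+DHEA and control came from 2 libraries that differed from each other. For genes of at least 5 CPM, an effect of IO+DHEA library 1 or 2 alone is argued against by the medians in the library not used to choose the genes. Genes over 4-fold apart between 1 IO+DHEA and 1 control library were measured in the other IO+DHEA library against the other control. Their median difference in the same direction was 1.005 to 1.39 on the log2 scale (lower 95% limit of the lowest 0.902). The same measure was 0.13 to 0.80 for etomoxir. The agreement was partial: 75.3% to 78.9% of the genes chosen in IO+DHEA kept their direction, against 55.1% to 75.4% in etomoxir. Over all 7610 genes of at least 5 CPM, Pearson's r between the separate differences was 0.336 to 0.374 for IO+DHEA and -0.03 to 0.28 for etomoxir. The 95% limits in this paragraph resample genes, which are not independent replicates, and leave out the spread between libraries. Loss of transcripts from library 1, where fewer genes were detected, is argued against for genes over 50 CPM, since those over 4-fold lower there fell by a median of 1.57 and 2.005 in library 2 against the other control (lower 95% limit of the first 1.29). At 5 to 50 CPM genes over 4-fold lower in library 1 fell by a median of 1.04 and 0.871 in library 2. Of these genes, 75.8% and 72.0% fell there too. Genes at 5 to 50 CPM that were over 4-fold lower in library 2 fell by a median of 1.72 and 1.27 in library 1. Loss was not judged at this level. Under 5 CPM it stays open: such genes had medians of 0.00 and 0.03 in library 2, and although 94.1% of the 101 changed genes stayed changed without library 1, a call already needs both libraries to move alike, so for these genes loss and a response cannot be told apart. Of the genes under 5 CPM that were over 4-fold lower in library 1, 47.3% and 50.3% fell in library 2. Genes at this level that were over 4-fold lower in library 2 fell by a median of 1.59 and 1.15 in library 1, where fewer genes were detected. Set against the other 5 libraries, the IO+DHEA pair gave 2615 genes and the other pairs at most 1. So 1 of 21 pairs gave as many, the smallest share these pairs allow and under the 0.05 level by a narrow margin. By construction each other pair leaves an IO+DHEA library in a group with other libraries. The share therefore shows only that the outlying libraries carried the same label, and no conclusion on chance is drawn from it. A response to the treatment may account for part of the change as a hypothesis, while a separate day or batch for this pair, which the labels do not give, stays open.

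ENSBTAG00000043960 was over 30-fold lower in both controls than in each treated library. A candidate explanation is that gaps of this size between any pair of libraries and the other 5 occur for some gene, whatever the treatment. The data fit this: 6 of 19 pairs other than the controls and the IO+DHEA pair had at least 1 gene with such a gap, so such a gap does not by itself point to the inhibitors. A response common to both inhibitors stays open, as does a difference between the parents of the embryos, which are not given in the sources used here. A separate day or batch for the controls, which the labels do not give, stays open too. The control titles are spelled differently from each other and hold a letter W that the treated titles lack, for which no reason is given.

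Fold changes of the treatments over the same controls were correlated, and the shared controls may account for most of this. The covariance of 0.493 was 0.017 and 0.120 with a separate control library for each treatment. The part due to shared controls, from the difference between the controls, was 0.424. That value follows from these covariances by algebra and is not separate evidence. Whether the remainder is a shared effect stays open: simulated unchanged groups gave a mean covariance of 0.576 with the spread of all 7 libraries and 0.367 with that of control and etomoxir, on either side of the observed value.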
